A study of Homo sapiens with 12 samples.

How the data were processed

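RNA sequencing libraries were made from 12 samples of dH1f cells, a line of fibroblasts derived from H1 human embryonic stem cells. Per the labels, the cells carried either a non-targeting control guide (NT) or a guide against MRG15, the protein product of the gene MORF4L1 (KO), and each kind was collected before OSKM and on day 6 of reprogramming. OSKM stands for OCT4 (gene POU5F1), SOX2, KLF4 and MYC, the transcription factors that turn somatic cells into induced pluripotent cells. The 4 groups held 3 replicates each. The labels do not say whether replicates are separate cultures or infections, so p-values measure only the spread between these samples.

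Per the labels' protocols, RNA was extracted with a Zymo Research kit and libraries were made with TruSeq Stranded mRNA chemistry. The submitters' processing notes name STAR, Salmon, DESeq2 and the genome build GRCh38. Their versions, the aligner settings and the annotation release are not given in the sources used here. The deposited table holds values on a log2 scale, made by the authors with the variance-stabilising transformation (VST) of DESeq2 from normalised gene counts. It lists 60660 gene identifiers in 12 libraries, and replicates are not pooled. On this scale the lowest value, 4.85, was shared by every library and stands for 0 reads, and 17064 identifiers had it in every library. Raw counts were not in the table. Alternative splicing, which the series also covers, was not analysed here.

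Normalised counts were estimated from the deposited values by inverting the transformation in its parametric form. That form was assumed, and the levels, folds and depths below depend on it. In each library 64.4 to 70.6% of the low values so obtained fell within 0.1 of a whole number after scaling, too few for a count model to be fitted. Levels given below as normalised counts are these estimates, and depth per library is the matching estimate of 17.87 to 22.23 M reads. Genes with a mean VST value at least 1 above the floor were tested, which left 14858 genes. A gene at this limit has an estimated 14.4 normalised counts, and genes below it were not tested. Gene symbols came from the identifiers, of which 14833 of those tested had one, and coordinates came from GENCODE release 29 on GRCh38.

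The difference between groups was tested for each gene with limma 3.58.1 in R 4.3.3, with the prior variance allowed to follow the mean (the trend option). All 4 groups were in 1 fit. The 5 comparisons were KO against NT before OSKM, KO against NT on day 6, day 6 against before OSKM in NT cells, the same in KO cells, and the difference between the KO effects on the 2 days (the interaction). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A difference is the difference of mean VST values on the log2 scale, with its SE, and is smaller than the log2 fold of the counts for genes near the floor. Replicate numbers were tested for pairing between groups, and correlations of the residuals of libraries with the same number, between -0.053 and 0.063, gave no ground for treating them as pairs.

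A set of 27 gene lists covering 592 genes was fixed before the data were examined, together with the comparisons, the tests, the alternatives and the rule for naming genes. Each list with at least 3 tested members was compared with all other genes by camera in limma, with a preset correlation of 0.01 between genes, and p-values were adjusted over the lists within a comparison. Camera was also run with a correlation estimated for each list, a setting that in limma also lowers the degrees of freedom of the test. The test fry, which takes a list on its own, was run beside it. For members of a list, counts are given over all genes tested and adjusted over the list alone.

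Genes were named by a rule. It takes MORF4L1, its paralog MORF4L2 and the 4 OSKM factors always, and the 8 highest and 8 lowest differences among called genes whose groups do not overlap, without clone-based names. It takes 5 and 5 for OSKM in KO cells, and for the interaction sets no condition on overlap. From each list it takes up to 4 called members with the largest differences, or the 2 with the highest mean where none was called. Some genes that the rule takes are left out of the text and figures.

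The alternatives were no filter, a filter at 2 above the floor, quantile normalisation, a shift of each library to a common median, the floor removed with a pseudocount of 1 or 10, limma with robust variances or without the trend, only the 2 groups compared, the replicate number as a block, and each of the 12 libraries left out in turn. Fits on log2 of the estimated counts with the same pseudocounts, and fits without the genes of chromosome 15, were chosen after seeing the data. The procedure was tested on simulated libraries, not on the real ones. Values were drawn with normal errors from each gene's mean and residual spread in these data, and differences were added to few of the genes. Simulated genes varied independently of each other, so the shares that follow need not hold for the real libraries. For KO against NT before OSKM the procedure recovered 82.1% of genes at a simulated difference of 0.5 and 100% at 1, and for the interaction 43.3% at 0.5 and 92.5% at 1. Of the calls for KO against NT before OSKM on these simulated data 2.6% were false. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.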

Results

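Messenger RNA was sequenced from dH1f fibroblasts that carried a non-targeting guide (NT) or a guide against MRG15 (KO), before OSKM (day 0) and on day 6 of reprogramming. Each of the 4 groups held 3 libraries. Estimated depth ran from 17.87 to 22.23 M reads per library, with group means of 21.1 (NT, day 0), 20.95 (KO, day 0), 21.4 (NT, day 6) and 18.8 M (KO, day 6). Transcripts of the mitochondrial genome took 4.18 to 5.53% of the estimated reads. The 10 most abundant genes took a mean of 14.2% in NT and 13.3% in KO cells on day 0, and 8.83% and 6.7% on day 6. The first principal component held 87.1% of the variance over the genes tested and separated the days, and the second, with 4.8%, separated KO from NT on both days. Levels below are estimated normalised counts, as mean ± SD of 3 libraries, and differences are in VST units (log2). For each gene named below as higher or lower in a comparison of 2 groups, the 3 libraries of one group all lay above the 3 of the other.

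**Figure D1:**
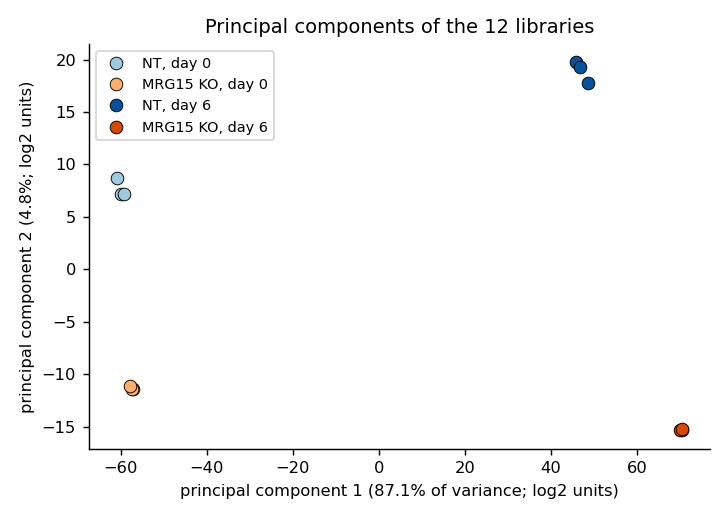
Principal components of the 12 libraries over the genes tested, with the first component (87.1% of the variance) on the horizontal axis and the second (4.8%) on the vertical axis, both in log2 units. Points are libraries, coloured by genotype and day, and the 3 libraries of each group lie together.

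MORF4L1, which encodes MRG15, a chromodomain protein that binds methylated lysine 36 of histone H3 and belongs to the NuA4 and SIN3 complexes, was checked first as the target of the guide. Its transcript (ENSG00000185787.15, GRCh38 chromosome 15, 78810487 to 78898133) stood at 7773 ± 90.4 in NT and 1338 ± 71.9 in KO cells on day 0, which is 82.8% lower. On day 6 it stood at 6956 ± 217 and 1020 ± 52.2, which is 85.3% lower. The differences were -2.49 (SE 0.05, adjusted p = 3.42e-13) and -2.70 (SE 0.05, adjusted p = 8.36e-14). All 6 KO libraries had less than any NT library. MORF4L1P1, a processed pseudogene on chromosome 1 that by its sequence can share reads with MORF4L1, was lower by a similar step on day 0, at 108.4 ± 17.8 against 473.3 ± 11.8. MORF4L2, the paralog that encodes MRGX, did not pass the test, with differences of -0.05 (adjusted p = 0.545) on day 0 and -0.07 (adjusted p = 0.326) on day 6. The list of MRG15, its paralog and their binding partners was not called on either day. Of its 14 genes 1 was higher and 2 were lower on day 0 (adjusted p = 0.601), and 3 were higher and 3 lower on day 6 (adjusted p = 0.578), with the same counts adjusted over the list alone. Genes of chromosome 15, on which MORF4L1 lies, were lower in KO cells as a group, with a median difference of -0.184 on day 0 and -0.109 on day 6 over 316 genes with a mean VST value of at least 8. The other 22 chromosomes with at least 50 such genes had medians of -0.028 to 0.032 and of -0.044 to 0.072.

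**Figure D2:**
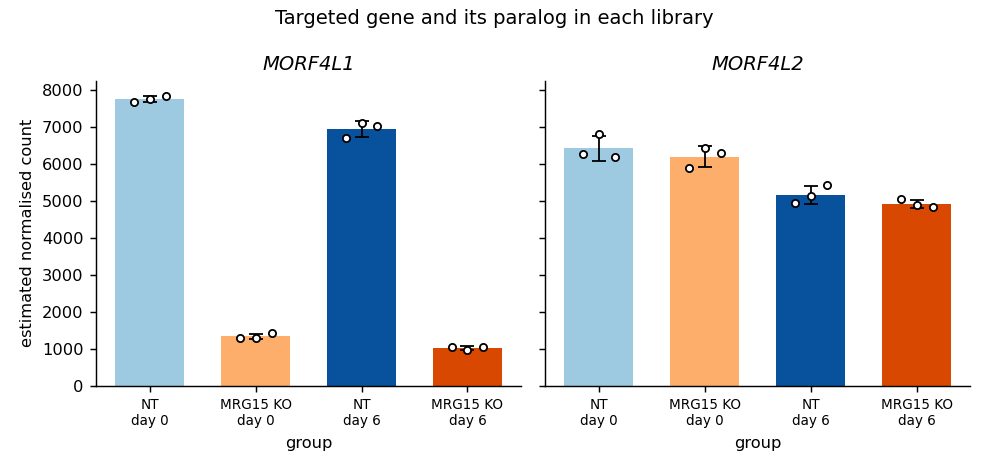
Estimated normalised counts of MORF4L1 and its paralog MORF4L2 in each group, with bars for the mean, points for the 3 libraries and error bars for the SD. MORF4L1 lies at 1338 and 1020 in the KO groups against 7773 and 6956 in the NT groups.

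**Figure D3:**
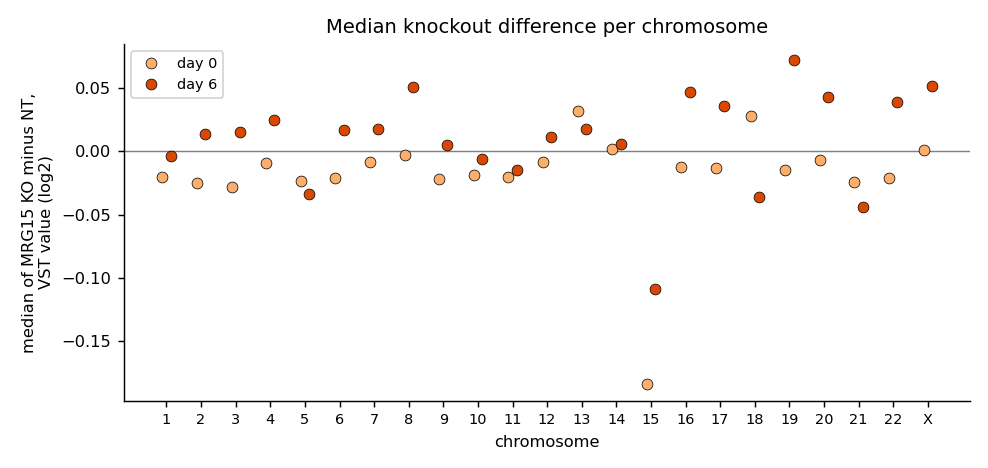
Median difference between KO and NT cells, in VST units (log2), over the genes of each chromosome with a mean VST value of at least 8, on day 0 and on day 6. Chromosome 15 lies at -0.184 and -0.109, below every other chromosome plotted on both days.

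The comparison of KO with NT cells on day 0 asks what differs with loss of MRG15 in fibroblasts before reprogramming begins. All KO libraries carry the same code in the labels, and no other guide and no rescue is among the samples. Other effects of that guide, or traits of that cell population, therefore cannot be told apart from loss of MRG15. Contractile genes and targets of TGF-β were lower in KO cells. ACTA2, smooth muscle actin, stood at 5619 ± 178 against 16565 ± 1108 (difference -1.55, SE 0.05, adjusted p = 9.29e-11), and TAGLN, an actin-binding protein, at 26409 ± 408 against 49589 ± 2484. The ligand TGFB2 fell by 1.03 (adjusted p = 5.72e-08). Cell cycle genes were higher, among them RRM2, a subunit of the enzyme that makes deoxyribonucleotides (0.62, SE 0.10, adjusted p = 5.58e-04). UHRF1, which helps copy DNA methylation (0.52), and the mitotic genes HMMR (0.83) and KIF11 (0.53) were higher too. Of the 22 TGF-β and contractile genes 17 were lower and 2 higher, with the same counts adjusted over the list alone (adjusted p = 6.86e-15, and adjusted p = 0.0225 with an estimated correlation). Of 26 G2/M genes 23 were higher and 0 lower, also adjusted over the list alone (adjusted p = 1.49e-17, and adjusted p = 0.0225 with an estimated correlation). Of 26 G1/S genes 13 were higher and 0 lower, and 19 were higher adjusted over the list alone (adjusted p = 3.42e-08, and adjusted p = 0.0225 with an estimated correlation).

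Among the individual genes that fell most were FLT1, a receptor for VEGF, at 55.8 ± 18.4 against 291.6 ± 23.2, and the collagen COL5A3 at 1190 ± 72.2 against 3836 ± 145. The matrix protein POSTN stood at 29723 ± 1111 against 78581 ± 4964, and the forkhead factor FOXS1 was lower too (-1.39, SE 0.09). CEMIP, a hyaluronan-degrading protein gene on chromosome 15 (median difference of its genes -0.184), fell by 1.41. RAB27B, a GTPase of secretory vesicles, was higher at 305.8 ± 13.8 against 69.3 ± 7.66. So were VGF, a neuropeptide precursor, at 104.4 ± 23.9 against 13.6 ± 0.672, and STMN2, a neuronal regulator of microtubules, at 96.5 ± 12.7 against 19.4 ± 9.15. The protease MMP3 (1.21, SE 0.12) and the transcription factors ATOH8 (1.16) and ETV1 (1.16) were also higher. Adjusted p for these 11 genes ran from 9.29e-11 (COL5A3) to 4.52e-05 (ETV1).

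Interferon-stimulated genes were lower in KO cells on day 0. IFI6, an interferon-induced mitochondrial protein, stood at 356.6 ± 55.8 against 907.3 ± 180 (difference -1.22, SE 0.13, adjusted p = 1.83e-05), and MX1, an antiviral GTPase, at 167.2 ± 45 against 471.5 ± 190 (difference -1.20, SE 0.22, adjusted p = 0.00155). OAS1, a sensor of double-stranded RNA, fell by 0.96. Of 27 interferon genes 18 were lower and 0 higher, and 21 were lower adjusted over the list alone (adjusted p = 7.1e-12, but adjusted p = 0.185 with an estimated correlation). The mean of the list was 7.72 to 8.16 in the 3 NT libraries and 7.28 to 7.52 in the 3 KO libraries.

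Genes of the unfolded protein and integrated stress responses were lower as well, among them TRIB3, a pseudokinase induced by ATF4 (-0.61, SE 0.10, adjusted p = 5.80e-04), and PSAT1, an enzyme of serine synthesis (-0.45). Another was CHAC1, a glutathione-degrading enzyme encoded on chromosome 15 (-0.72, with a median difference of that chromosome of -0.184). In that list 12 of 23 genes were lower and 0 higher, and 15 were lower adjusted over the list alone (adjusted p = 8.83e-08, but adjusted p = 0.0805 with an estimated correlation). Of 30 fibroblast and mesenchymal genes 12 were lower and 3 higher, and 14 and 4 adjusted over the list alone (adjusted p = 9.37e-06, but adjusted p = 0.0805 with an estimated correlation). SPARC, a collagen-binding matrix protein, was among the lower (-0.90, SE 0.04), and DCN, a proteoglycan, among the higher (0.71, SE 0.09). NCAM1, a neural adhesion molecule, rose by 0.82 in the list of neural progenitor markers, of whose 5 tested genes 3 were higher, also adjusted over the list alone (adjusted p = 0.0179, but adjusted p = 0.0837 with an estimated correlation). BRMS1 rose by 0.54 in the list of the SIN3 histone deacetylase complex, of whose 18 genes 2 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0157, but adjusted p = 0.0805 with an estimated correlation). None of the 4 reprogramming factors was called on day 0 (POU5F1 0.22, adjusted p = 0.296, SOX2 -0.19, adjusted p = 0.146, KLF4 -0.05, adjusted p = 0.538, and MYC -0.11, adjusted p = 0.145).

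In all, 2698 of 14858 genes were called between KO and NT on day 0, 1102 higher and 1596 lower in KO cells (1235 and 1217 after quantile normalisation). The groups did not overlap for 4995 genes (33.6%), where chance gives 10%. Of the 14 lists called, 3 held with an estimated correlation, and for the lists named here that p was the highest over their alternatives, which began at 7.34e-18 for G2/M.

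Day 6 against day 0 in NT cells compares fibroblasts with MRG15 in place before OSKM and on day 6 of reprogramming. No day 6 culture without OSKM was among the samples. Time in culture and any other difference between the days therefore cannot be told apart from OSKM. What is called the OSKM change here is this difference between the days. The 4 factors rose, POU5F1 from 0.443 ± 0.767 to 4018 ± 71.7 and SOX2 from 0.729 ± 0.632 to 5216 ± 264. KLF4 rose from 362.1 ± 4.79 to 16535 ± 273 and MYC from 2074 ± 63 to 15556 ± 308, with adjusted p from 1.17e-18 (KLF4) to 4.13e-15 (POU5F1). These reads do not tell introduced from endogenous transcripts. Genes of the pluripotency network rose with them, among them L1TD1, an RNA-binding protein of pluripotent cells, from 23.4 ± 13 to 2144 ± 115 (difference 5.03, SE 0.13, adjusted p = 1.28e-13). TDGF1, a co-receptor for NODAL, rose from 0.352 ± 0.609 to 824.8 ± 52.3, and the noncoding RNA ESRG by 6.06. Epithelial genes rose too, such as CDH1, which encodes E-cadherin, from 11.1 ± 5.3 to 467.3 ± 26.6 and the tight junction gene CLDN7 (2.62, SE 0.13). Fibroblast and contractile genes fell, such as FN1, which encodes fibronectin (-2.29, SE 0.05, adjusted p = 7.97e-15). Pluripotency genes rose in 17 of 17 cases (adjusted p = 5.86e-11) and epithelial genes in 19 of 23 with 4 lower (adjusted p = 1.89e-05). Only 17 of 27 pluripotency and 23 of 30 epithelial genes on the lists passed the filter. The filter uses the mean over all 12 libraries, so a gene near 0 on day 0 was tested only if higher on day 6. For such genes a rise was largely fixed in advance, so these results cannot show how much of the whole list rose. G1/S genes rose in 24 of 26 (adjusted p = 2.18e-08) and G2/M genes in 26 of 26 (adjusted p = 1.64e-11). Fibroblast genes fell in 26 of 30 cases with 3 higher (adjusted p = 2.09e-09), and TGF-β and contractile genes in 21 of 22 (adjusted p = 1.02e-11). Counts adjusted over the list alone were the same for these 6 lists, and each had adjusted p = 0.0184 with an estimated correlation, the highest over its alternatives.

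The keratins of stratified epithelium were among the genes that rose most in NT cells, with KRT14 from 3.39 ± 1.76 to 14732 ± 341 and KRT16 from 2.05 ± 0.445 to 5366 ± 226. Keratinocyte markers rose in 8 of 11 cases with 1 lower, also adjusted over the list alone (adjusted p = 1.28e-04, and adjusted p = 0.0225 with an estimated correlation). Of the 14 members of that list 11 were tested, under the limit of the filter given above. IGF2, an imprinted growth factor, rose from 43.9 ± 3.07 to 47906 ± 3087 (difference 9.02, SE 0.08), and TUBB4A, a brain β-tubulin, from 1.79 ± 2.23 to 7714 ± 261. Among the genes that fell most were the collagenase MMP1, from 2919 ± 311 to 58.8 ± 8.42, the oxytocin receptor OXTR, from 5731 ± 382 to 242.2 ± 37.8, and the pentraxin PTX3 (-3.47, SE 0.07). Genes of oxidative phosphorylation rose in 27 of 31 cases and in 28 adjusted over the list alone (adjusted p = 1.77e-07, but adjusted p = 0.169 with an estimated correlation). Ribosomal protein genes fell in 16 of 28 cases and in 13 adjusted over the list alone (adjusted p = 0.0044, but adjusted p = 0.585 with an estimated correlation). This direction turned to higher after quantile normalisation (adjusted p = 0.00458, range over alternatives 5.07e-04 to 0.585). Of 14858 genes 9923 were called, 4998 higher and 4925 lower on day 6. The groups did not overlap for 10343 (69.6%, where chance gives 10%), and 9 of the 17 lists called held with an estimated correlation.

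The same comparison in KO cells, with the same limit, asks how the days differ where MRG15 is depleted. POU5F1 rose from 2.62 ± 3.61 to 6211 ± 141 and SOX2 from 0 in all 3 libraries to 8092 ± 306. KLF4 (5.55, SE 0.04) and MYC (3.11, SE 0.05) rose too. L1TD1 rose from 18.2 ± 3.5 to 3151 ± 254 and TDGF1 from 5.17 ± 8.96 to 1268 ± 21.2. The calcium-binding protein CALB1, from 3.90 ± 2.87 to 6380 ± 6.84, was with TUBB4A (9.08), SOX2 (8.14), IGF2 (7.90) and POU5F1 (7.44) among the 5 named genes with the highest differences. Among the genes that fell were GREM1, a BMP antagonist on chromosome 15 (-5.22, SE 0.04), MMP1 (-5.09), PTX3 (-4.83) and OXTR (-4.74), with adjusted p from 2.27e-19 (GREM1) to 8.04e-15 (MMP1). Pluripotency genes rose in 17 of 17 cases (adjusted p = 2.06e-09), epithelial genes in 19 of 23 with 3 lower (adjusted p = 4.78e-05) and G1/S genes in 24 of 26 (adjusted p = 7.16e-08). As in NT cells, the filter largely fixed in advance the rise of genes near 0 on day 0. Fibroblast genes fell in 28 of 30 with 2 higher (adjusted p = 4.94e-12) and TGF-β and contractile genes in 22 of 22 (adjusted p = 2.26e-12). Counts adjusted over the list alone were the same for these 5 lists, and each had adjusted p = 0.017 with an estimated correlation, the highest over its alternatives. Interferon genes rose in 19 of 27 cases with 3 lower, also adjusted over the list alone (adjusted p = 7.30e-04, but adjusted p = 0.445 with an estimated correlation). Of 14858 genes 10969 were called, 5590 higher and 5379 lower on day 6. The groups did not overlap for 11345 (76.4%, where chance gives 10%), and 6 of the 16 lists called held with an estimated correlation.

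Across genes, which are not independent replicates, the OSKM change in KO cells followed that in NT cells with Pearson's r of 0.947, Spearman's rho of 0.923 and a slope of 1.118. Both genotypes called 4509 genes higher (1880.4 expected if calls were independent) and 4350 lower (1783 expected), and 46 and 28 genes were called in opposite directions.

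KO against NT on day 6 asks what differs with loss of MRG15 during reprogramming, under the limit of the guide given for day 0. Fibroblast and contractile genes were lower in KO cells, with COL1A1, the main chain of type I collagen, at 79961 ± 4788 against 277602 ± 14215 (difference -1.80, SE 0.05, adjusted p = 3.89e-12). ACTA2 stood at 1270 ± 38.9 against 6617 ± 221 and TAGLN at 2183 ± 134 against 10265 ± 589. DNMT3L, a cofactor of the de novo DNA methyltransferases, was higher at 1022 ± 36.1 against 295.9 ± 66.6 (3.45-fold, adjusted p = 7.46e-08), and DNMT3B, one of those enzymes, was 0.82 higher (SE 0.10, adjusted p = 1.09e-05). Keratins of stratified epithelium were lower, with KRT17 at 529 ± 23.5 against 3013 ± 195 and KRT16 at 1697 ± 53.6 against 5366 ± 226. Fibroblast genes were lower in 25 of 30 cases and in 26 adjusted over the list alone, with 0 higher (adjusted p = 1.51e-24, and adjusted p = 0.00423 with an estimated correlation). TGF-β and contractile genes were lower in 21 of 22 with 0 higher, also adjusted over the list alone (adjusted p = 1.86e-24, and adjusted p = 0.00526 with an estimated correlation). Keratinocyte markers were lower in 9 of 11 and in 10 adjusted over the list alone, with 0 higher (adjusted p = 1.16e-07, and adjusted p = 0.00745 with an estimated correlation). Pluripotency genes were higher in 9 of 17 with 1 lower, also adjusted over the list alone (adjusted p = 0.00377, but adjusted p = 0.156 with an estimated correlation).

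The reprogramming factors were higher in KO cells on day 6, with POU5F1 at 6211 ± 141 against 4018 ± 71.7 (1.55-fold, difference 0.62, adjusted p = 0.00234). SOX2 stood at 8092 ± 306 against 5216 ± 264 (1.55-fold, difference 0.63, adjusted p = 4.08e-05) and KLF4 at 18998 ± 858 against 16535 ± 273 (1.15-fold, difference 0.20, adjusted p = 0.00271). MYC stood at 17088 ± 615 against 15556 ± 308 (1.1-fold, adjusted p = 0.0375). Its call ended without NT replicate 1 (0.056), 2 (0.11) or 3 (0.0793) or KO replicate 2 (0.0748) or 3 (0.144) of day 6, with a range over alternatives of 0.0113 to 0.144. The calls of POU5F1 and SOX2 ended with the floor removed and a pseudocount of 1 (adjusted p = 0.631, range 1.90e-06 to 0.631, and adjusted p = 0.399, range 5.01e-06 to 0.399), and that of POU5F1 also with a pseudocount of 10 (0.0933) and on estimated counts plus 1 (0.394). The list of the 4 factors, all called higher and also adjusted over the list alone, had adjusted p = 0.011, but adjusted p = 0.16 with an estimated correlation. LIN28A, an RNA-binding protein of pluripotent cells, was higher at 311 against 81.4 (adjusted p = 6.14e-07). Its call also ended with the floor removed and a pseudocount of 1 (adjusted p = 0.136, range 1.48e-07 to 0.136). In VST units, with only the 2 groups of day 6 compared, the calls of POU5F1, SOX2 and LIN28A held. The fits that ended them kept all 4 groups, with day 0 counts of up to 6.74 for POU5F1 and 1.11 for SOX2. Whether these low counts ended the calls was not tested. CLDN7 was 1.04 higher in KO cells (SE 0.13), while the epithelial list was not called, with 8 of 23 genes higher and 2 lower, also adjusted over the list alone (adjusted p = 0.113).

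**Figure D4:**
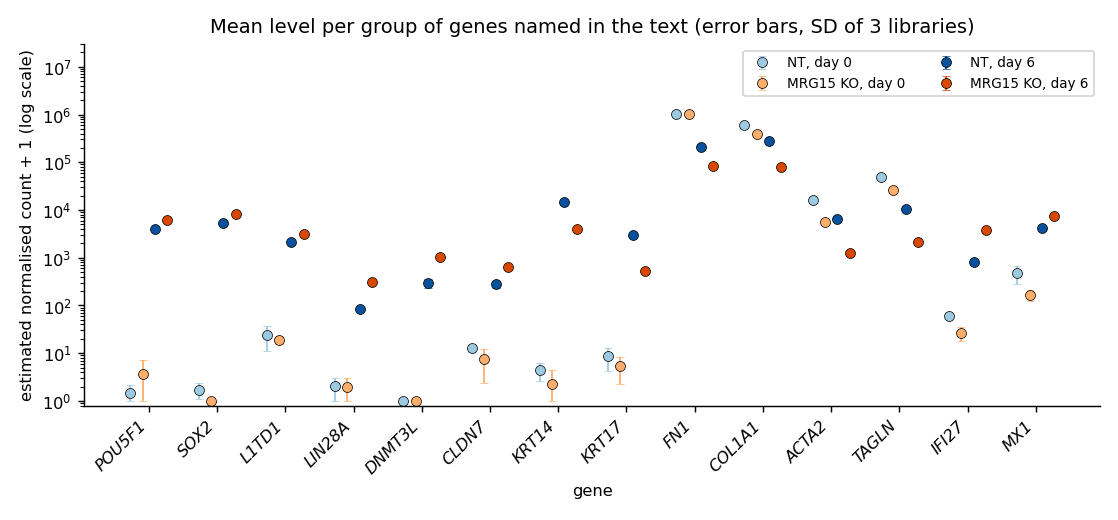
Mean estimated normalised count plus 1, on a log scale, of genes named in the text in the 4 groups, with error bars for the SD of 3 libraries. On day 6 POU5F1 lies at 4018 in NT and 6211 in KO cells, COL1A1 at 277602 and 79961, and KRT17 at 3013 and 529.

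Proliferation genes were higher in KO cells on day 6 as on day 0, among them CDT1, which licenses replication origins (0.69, SE 0.12, adjusted p = 3.55e-04), the helicase subunit MCM7 (0.64), the transcription factor E2F1 (0.55) and the kinetochore gene NDC80 (0.70). G1/S genes were higher in 22 of 26 cases and in 23 adjusted over the list alone, with 0 lower (adjusted p = 1.97e-10, and adjusted p = 0.00745 with an estimated correlation). G2/M genes were higher in 19 of 26 with 0 lower, also adjusted over the list alone (adjusted p = 6.04e-07, but adjusted p = 0.0868 with an estimated correlation). Genes of the senescence secretory list were lower, with IGFBP7, a secreted binding protein of insulin-like growth factors, at 1668 ± 30.6 against 5153 ± 292 and IGFBP5 1.25 lower (difference -1.25, SE 0.06). In that list 13 of 22 genes were lower and 1 higher, also adjusted over the list alone (adjusted p = 3.06e-06, and adjusted p = 0.0479 with an estimated correlation). Stress response genes were lower, with TRIB3 at 664 ± 20.6 against 1538 ± 30.1 and 17 of 23 genes lower and 0 higher, also adjusted over the list alone (adjusted p = 4.69e-07, but adjusted p = 0.092 with an estimated correlation).

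IFI27, an interferon-induced gene, was 4.55-fold higher in KO cells on day 6, at 3754 ± 190 against 824.8 ± 132 (difference 2.12, SE 0.12, adjusted p = 3.44e-09). IFI6 (0.85, SE 0.13, adjusted p = 1.48e-04) and HERC5, a ligase for the interferon-induced modifier ISG15 (1.03, SE 0.15, adjusted p = 7.29e-05), were higher as well. The interferon list was not called on day 6, with 7 of 27 genes higher and 1 lower, also adjusted over the list alone, a median of -0.013, a mean of 0.187 and a test direction of higher (adjusted p = 0.241). Other genes with high differences were LHX9, a LIM homeobox factor, at 311 ± 27.1 against 86.3 ± 18.1, and RHBDL3, a rhomboid-like protein, at 529 ± 71.4 against 164.9 ± 18.5. Among those that fell most were HAPLN1, a hyaluronan link protein (-2.47, SE 0.16), and a pair of chromosome 15 genes (median difference of that chromosome -0.109), the matrix protein THBS1 (-2.63, SE 0.05) and the collagen receptor ITGA11 (-2.21, SE 0.11). Of 14858 genes 5487 were called, 2636 higher and 2851 lower in KO cells (3120 and 2692 after quantile normalisation, 2938 and 2658 with equal library medians), and the groups did not overlap for 7372 (49.6%, where chance gives 10%). Of the 16 lists called, 5 held with an estimated correlation, and that p was the highest over the alternatives of each of the 16, which began at 1.18e-25 for the fibroblast list.

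**Figure D5:**
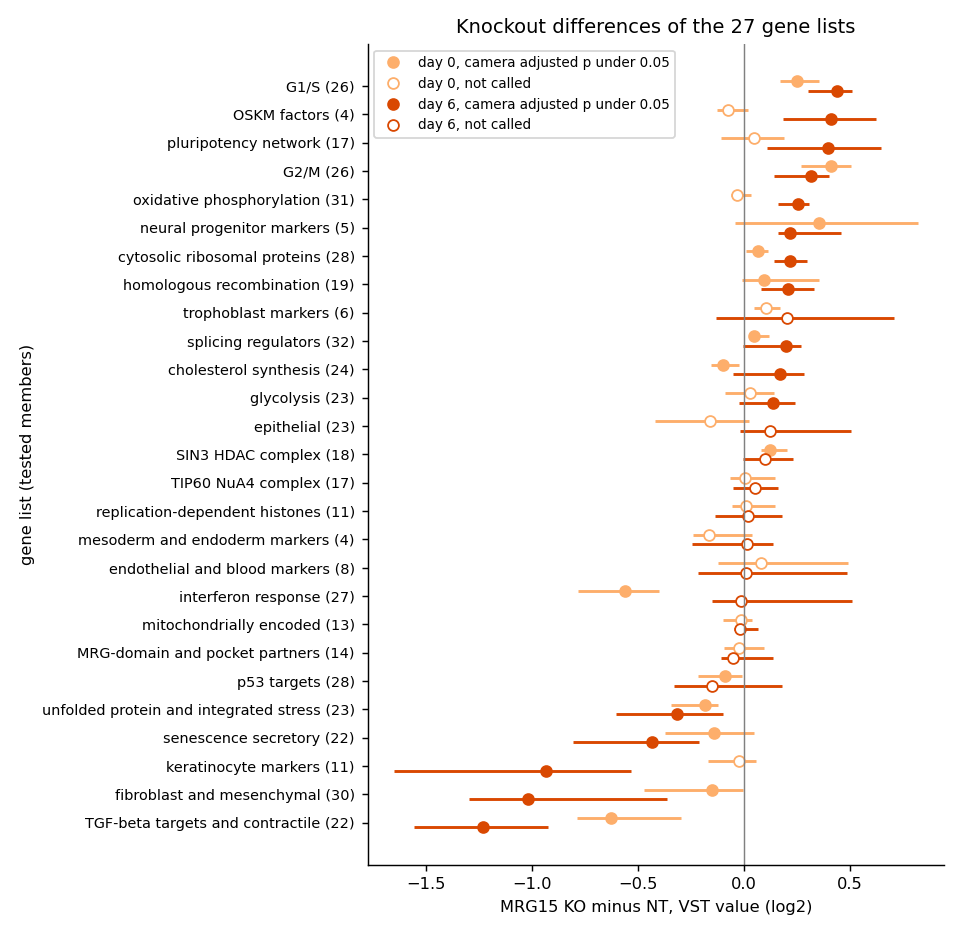
Median difference between KO and NT cells, in VST units (log2), of the 27 gene lists on day 0 and day 6, with lines from the lower to the upper quartile and filled points where camera called the list. TGF-β and contractile genes have medians of -0.629 and -1.23, and G1/S genes of 0.25 and 0.44.

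The interaction asks whether the difference between KO and NT cells changed from day 0 to day 6. Fibroblast genes fell further in KO cells than in NT cells, among them the proteoglycan LUM (-1.44, SE 0.09, adjusted p = 8.73e-08), and the collagen COL6A3 (-1.38, SE 0.07). So did the gelatinase MMP2 (-1.37, SE 0.07) and SNAI2, a transcription factor of mesenchymal cells (-1.36, SE 0.07). TAGLN in the TGF-β list also had a negative interaction (-1.30, SE 0.08), and the keratinocyte markers KRT17 (-2.21, SE 0.17) and KRT16 (-1.55, SE 0.11) rose less in KO cells. Interferon genes moved the other way, with positive interactions of IFI27 (2.74, SE 0.16, adjusted p = 4.93e-08), IFI6 (2.07, SE 0.18, adjusted p = 2.94e-06) and OAS1 (1.76, SE 0.21). The fibroblast list had 23 of 30 genes with a negative interaction, 24 adjusted over the list alone, and 0 with a positive one (adjusted p = 3.42e-24, and adjusted p = 0.00445 with an estimated correlation). The TGF-β list had 16 of 22 negative, 17 adjusted over the list alone, and 1 positive (adjusted p = 4.47e-16, and adjusted p = 0.0138 with an estimated correlation). Keratinocyte markers had 8 of 11 negative, 9 adjusted over the list alone, and 0 positive (adjusted p = 4.71e-09, and adjusted p = 0.00677 with an estimated correlation). Of these, KRT14, KRT6A, KRT16, KRT17 and DSG3 lay near the floor on day 0 in both genotypes, with means from 0.585 to 7.65. They could hardly differ then, so their interaction largely repeats the difference of day 6. Interferon genes had 14 of 27 positive, 17 adjusted over the list alone, and 0 negative (adjusted p = 4.47e-09, but adjusted p = 0.259 with an estimated correlation).

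SOX2 rose further in KO cells (0.81, SE 0.12, adjusted p = 2.29e-04), while POU5F1 did not pass the test (0.40, SE 0.19, adjusted p = 0.162). On day 6 both were higher in KO cells by the same fold. Their day 0 counts lay near the floor, from 0 to 1.11 for SOX2 and from 0 to 6.74 for POU5F1. The contrast between them thus does not show that they respond differently to the knockout. DNMT3L, 0 in both genotypes on day 0, had an interaction of 1.64 (SE 0.17, adjusted p = 9.60e-06), and the epithelial junction genes CLDN7 (1.30, SE 0.19) and OCLN (1.28, SE 0.20) rose further in KO cells too. CPA4, a carboxypeptidase (-2.34, SE 0.11), RAB27B (-2.08, SE 0.14) and GREM1 (-1.85, SE 0.06) had the reverse sign, the last on chromosome 15, where the median difference was -0.184 on day 0 and -0.109 on day 6. Of 14858 genes 3017 had a called interaction, 1348 positive and 1669 negative. Of the 13 lists called, 3 held with an estimated correlation, and that p was the highest over the alternatives of each of the 13, which began at 1.10e-25 for the fibroblast list.

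Across genes, which are not independent replicates, the KO differences of the 2 days had Pearson's r of 0.33 and Spearman's rho of 0.299. They shared 391 genes called higher (195.5 expected if calls were independent) and 905 called lower (306.2 expected), while 172 were higher on day 0 and lower on day 6 and 102 the reverse. COL5A3 and POSTN were among the named genes lower in KO cells on both days, at 886 ± 23.2 against 3061 ± 102 and 8518 ± 266 against 29368 ± 802 on day 6.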

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

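Except for the test of a fibroblast program on chromosome 15 and the other splits of the samples, the tests in this part were chosen only after the result was seen. The intervals in this part come from resampling genes, which are not independent replicates, and do not measure the spread between libraries.

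The difference between KO and NT cells changed from day 0 to day 6 for 3017 genes and 13 gene lists by the test of the interaction, of which 3 lists held with an estimated correlation. Of 100 splits drawn from 200 possible ones 2 gave at least as many genes, the real one included, a share under 0.05. The splits mix KO and NT libraries within a day, so they bear on any difference between KO and NT. They cannot decide whether that difference changed between the days, and no conclusion on the interaction is drawn from them. The highest of the other splits called 5376 genes: it exchanged the genotypes on day 0 only, so its interaction is the sum of the KO differences of both days and it points to that structure of the samples.

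Genes of chromosome 15 were lower in KO cells in 76.9% of 316 cases on day 0 and 67.7% on day 6, where no other chromosome passed 60.6% and 58.6% (120 called lower and 13 higher on day 0, and 114 lower and 32 higher on day 6). The difference from all other genes was -0.151 to -0.171 in the 3 KO libraries of day 0 and -0.123 to -0.151 in those of day 6, against -0.016 to 0.001 in the 6 NT libraries. A fibroblast program was argued against, since 110 of these genes that OSKM left nearly unchanged and that are on no list had a median of -0.181 (95% bootstrap interval -0.207 to -0.125), below the -0.049 that bounds the other chromosomes. A local effect near the targeted site was argued against as the whole cause too, since 231 genes over 10 Mb away had a median of -0.166 (interval -0.196 to -0.127). A candidate explanation that stays open is a difference in copies of chromosome 15 in part of the cells, which the 76.9% prompted and so cannot test, with medians of -0.175 before and -0.207 after MORF4L1, and relative levels do not say which genotype changed.

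KO cells lay further along the OSKM change on day 6, at 1.157 ± 0.003 of the way from the NT mean of day 0 to that of day 6 (NT libraries placed without themselves 0.986 ± 0.016, SD, n = 3), and in VST units falling genes carried more of this, with 684 of 1071 lower in KO cells and 20 higher, than rising ones, with 524 of 1300 higher and 162 lower. Fewer cells that OSKM did not reach among the KO cells would move all of them by one share. This was checked on the linear scale, among genes not called and under 0.2 apart on day 0. The 458 that fell went a median of 12.3% further (interval 11.2 to 14.3, quartiles 4.9 to 21.1). The 763 that rose went 27.1% further (interval 22.4 to 31.3, quartiles -5.1 to 58.3). Over all 1071 and 1300 genes the medians were 13.2% and 24.7%. Judged by the spread over genes alone, this argues against fewer such cells as the whole cause. The KO difference of day 0 added to the OSKM change is argued against as well, since the lowest KO library of day 6 lay 0.151 above the highest NT library, and the largest shift on day 0 was 0.034. Higher OSKM levels in KO cells, with a mean difference of 0.4 over the 4 factors, may account for the pattern or follow from it, and this cannot be told apart from genotype, with which it moves. An effect of MRG15 loss on reprogramming, the difference the design names, stays among the open explanations as untested.

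Keratins of stratified epithelium rose from day 0 to day 6 in NT cells and were lower in KO cells on day 6, with KRT14 at 4056 ± 128 against 14732 ± 341 (adjusted p = 1.71e-08, range over alternatives 3.91e-10 to 0.0598). Keratinocytes among the NT cells were argued against as the whole cause, because KRT5, the abundant partner of KRT14 in basal keratinocytes, reached at most 0.73% of the KRT14 level, at 98.8 against 14732, although DSG3 (1.11 to 107.8), LAMB3 (372.3 to 1846) and TRIM29 (253.8 to 572.1) rose in NT cells from day 0 to day 6 as well. Reads moved between keratin genes by their assignment were argued against as the whole cause, since the counts summed over 205 keratin genes and pseudogenes were lower too, at 39709 ± 710 in KO against 58723 ± 2077 in NT cells (log2 ratio -0.56). KRT14, KRT6A (11043 in NT, 3415 in KO) and KRT16 (5366 and 1697) together fell by more than this sum. The other keratins were thus higher together in KO cells, and reads moved as a part of the cause are not excluded. A fall in one keratin that spills over to its paralogs stays open for the keratins, though it does not reach the 6 tested markers that are not keratins, of which 5 were lower in KO cells (median -0.57). A candidate explanation left open is that MRG15 loss changes which genes OSKM switches on, and no test of it was available in these groups.

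The medians of the interaction over the 13 lists were 0.32 for OSKM factors, 0.31 for the pluripotency network, 0.38 for epithelial genes, -0.72 for fibroblast genes, -0.72 for TGF-β and contractile genes, 0.22 for G1/S genes and -0.32 for the senescence secretory list. They were 0.57 for interferon genes, 0.25 for oxidative phosphorylation, -0.17 for the unfolded protein and integrated stress responses, 0.28 for cholesterol synthesis, -0.92 for keratinocyte markers and 0.16 for ribosomal proteins. The fibroblast, TGF-β and keratinocyte lists held with an estimated correlation, and the other 10 lost their call, with adjusted p = 0.183 to 0.521 with an estimated correlation. The stress response call, with adjusted p = 0.0364, ended without NT replicate 1 (0.0968), KO replicate 1 (0.0713) or KO replicate 3 (0.0852) of day 0, or NT replicate 2 (0.0615) or KO replicate 2 (0.0528) of day 6. It had adjusted p = 0.513 with an estimated correlation, the highest over its alternatives, which began at 0.00274.

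Named genes with a positive interaction, in VST units (log2), were IFI27 at 2.74, IFI6 at 2.07, MX1 at 2.03, RGS5 at 2.02, OAS1 at 1.76, ALPG, a gene with near-identical paralogs, at 1.67, DNMT3L at 1.64, and ESAM at 1.6. Others were LIN28A at 1.47, CLDN7 at 1.30, OCLN at 1.28, EPCAM at 1.05, SOX2 at 0.81, KLF4 at 0.24 and MYC at 0.24. Those with a negative one were CPA4 at -2.34, KRT17 at -2.21, RAB27B at -2.08, the pseudogene PKD1P5 at -1.90 and GREM1 at -1.85. Next were SERPINB7 at -1.72, KRT6A at -1.71, KRT16 at -1.55, KRT14 at -1.54 and ITGA11 at -1.51. Further negative ones were LUM at -1.44, MMP3 at -1.41, COL6A3 at -1.38, MMP2 at -1.37, SNAI2 at -1.36, TAGLN at -1.30, LTBP2 at -1.29, IGFBP5 at -1.13, KRT7 at -1.11, STMN2 at -1.08, NCAM1 at -1.0 and MORF4L1 at -0.21. MYC, with adjusted p = 0.0205, lost its call without KO replicate 3 of day 6 (0.0562, range over alternatives 0.0145 to 0.0693), and KLF4 with no filter (0.0549, range 0.00463 to 0.0549). With the floor removed and a pseudocount of 1 the calls of LIN28A (adjusted p = 0.349, range 1.35e-05 to 0.349), KRT6A (0.353, range 1.49e-06 to 0.353) and KRT14 (0.78, range 1.20e-06 to 0.78) ended, that of KRT14 with its direction turned (-1.54 to 0.49). MORF4L1, with adjusted p = 0.0471, lost it without NT replicate 1 (0.0871), 2 (0.0787) or 3 (0.0589) or KO replicate 2 (0.0525) or 3 (0.116) of day 0. It also lost it without NT replicate 2 (0.0978) or 3 (0.0928) or KO replicate 2 (0.104) or 3 (0.0592) of day 6, with a range over alternatives of 0.000205 to 0.145.

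The real split of the 6 libraries gave 2698 genes for KO against NT on day 0 and 5487 on day 6, where the highest of the other splits gave 0 and 1. For day 6 against day 0 it gave 9923 genes in NT and 10969 in KO cells, where the highest other gave 0 in both. In each of these 4 comparisons 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.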

How the results depend on the processing

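In this part, the fits on estimated counts and those without the genes of chromosome 15 were chosen only after the result was seen. The 5 counts of called genes stayed within 1.5 times the reported ones under every alternative run, between 1924 and 2698 for KO against NT on day 0 and 4520 and 5812 on day 6. The ranges were 8529 and 10672 for OSKM in NT cells, 9357 and 12165 in KO cells, and 2173 and 3209 for the interaction. With each library left out in turn they ran from 1924 to 2691, 4520 to 5643, 9349 to 9931, 10474 to 11039 and 2425 to 3051. With the replicate number as a block they were 2633, 5470, 9945, 10991 and 2953, and without chromosome 15 they were 2530, 5323, 9594, 10607 and 2940. Which direction held more calls depended on the scaling: for KO against NT, 40.8% of calls were higher on day 0 and 48% on day 6 as reported, 50.4% and 53.7% after quantile normalisation, and 41.5% and 52.5% with equal library medians. Over all alternatives the share of higher calls ran from 46.2 to 54.4% for OSKM in NT cells, 49.1 to 53.8% in KO cells and 40.4 to 49.6% for the interaction. At this depth 1 read stands for 0.864 to 1.14 normalised counts, genes below the filter at 14.4 were not tested in the reported comparisons, and the scalings moved the median of all genes by less than 0.1.

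Among the camera alternatives, list calls changed most in the setting with an estimated correlation. There 3 of 14 lists were called for KO against NT on day 0 and 5 of 16 on day 6. For OSKM 9 of 17 were called in NT cells and 6 of 16 in KO cells, and for the interaction 3 of 13. This setting changes the correlation and the degrees of freedom together. On day 0 the SIN3 list lost its call (adjusted p = 0.0157 to 0.0805) with an estimated correlation of -0.015, below the preset 0.01. So did the homologous recombination list, at -0.01. Lost calls therefore cannot be put down to correlation between genes alone. With the replicate number as a block the neural progenitor list lost its call on day 6 (0.0594, range over the camera alternatives 0.0394 to 0.138) and for OSKM in KO cells (0.0659, range 0.0376 to 0.152). With fry, which does not compare a list with other genes, 17 lists were called for KO against NT on day 0 and 22 on day 6. It called 26 for OSKM in NT cells, 24 in KO cells and 13 for the interaction. With each library left out in turn the counts of lists ran from 10 to 14, 15 to 17, 17 to 19, 15 to 17 and 12 to 13.

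Across genes, r between the KO differences of the 2 days, 0.33 as reported, was 0.231 with no filter, 0.358 with the stricter filter, 0.305 after quantile normalisation and 0.32 without chromosome 15, and the 0.947 between the OSKM changes became 0.914, 0.951 and 0.942 in the first 3 of these. The cause was not tested, and the filter settings change which genes are compared.

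Quantile normalisation reversed the OSKM change of MORF4L1 in NT cells (-0.16 to 0.1), of RPL15 in NT cells (-0.37 to 0.16) and of RPS18 in NT (-0.35 to 0.07) and KO cells (-0.29 to 0.1). The ribosomal protein list in NT cells turned from lower to higher (adjusted p = 0.00458, range 5.07e-04 to 0.585). For these the cause was not tested. With the floor removed and a pseudocount of 1 the interaction reversed for LEFTY2 (-0.82 to 0.17), ERVW-1 (0.77 to -0.05) and KRT14 (-1.54 to 0.49), and the cause was not tested. KRT14 lay near the floor on day 0, at 3.39 ± 1.76 in NT and 1.25 ± 2.16 in KO cells, where this setting enlarges differences. Of the named genes called in a comparison, 65 of 88 (KO against NT on day 0), 86 of 107 (day 6), 109 of 117 (OSKM in NT cells), 114 of 116 (OSKM in KO cells) and 64 of 93 (interaction) kept their call and direction under every alternative that tested them. The filter at 2 above the floor tested only 81, 98, 106, 104 and 87 of them, in the same order. Fits without chromosome 15 did not test the genes on it.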

Other observations

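Nothing in this part rests on a test chosen only after the result was seen. On day 6 genes of oxidative phosphorylation were higher in KO cells, among them NDUFV1, a subunit of complex I (0.60, SE 0.05, adjusted p = 4.32e-07). In this list 23 of 31 genes were higher and 0 lower, and 24 were higher adjusted over the list alone (adjusted p = 5.56e-08, but adjusted p = 0.16 with an estimated correlation). On day 0 the same list was not called, with 3 genes higher and 2 lower, also adjusted over the list alone (adjusted p = 0.887). Its interaction had 15 genes positive and 0 negative, 18 positive adjusted over the list alone (adjusted p = 3.64e-08, but adjusted p = 0.222 with an estimated correlation). Cholesterol synthesis genes were higher on day 6 in 9 of 24 cases with 2 lower, and 10 and 3 adjusted over the list alone (adjusted p = 0.027, but adjusted p = 0.327 with an estimated correlation). Their interaction had 12 positive and 0 negative, 13 positive adjusted over the list alone (adjusted p = 3.46e-05, but adjusted p = 0.183 with an estimated correlation). Ribosomal protein genes were higher on day 6 in 23 of 28 cases with 1 lower, and in 25 adjusted over the list alone (adjusted p = 5.56e-08, but adjusted p = 0.31 with an estimated correlation). Splicing regulators were higher on day 6 in 16 of 32 cases with 2 lower, also adjusted over the list alone (adjusted p = 0.00168, but adjusted p = 0.11 with an estimated correlation). Neural progenitor markers were higher in 3 of 5 with 0 lower, also adjusted over the list alone (adjusted p = 0.0416, but adjusted p = 0.138 with an estimated correlation). The replicate number as a block ended this call too (adjusted p = 0.0594, range over the camera alternatives 0.0394 to 0.138). NES, an intermediate filament of neural stem cells, was among them (0.46, SE 0.05).

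Several lists passed the test for KO against NT narrowly, and leaving out 1 library ended their calls. On day 0 genes of the senescence secretory list were lower in 7 of 22 cases with 2 higher, also adjusted over the list alone, such as IGFBP3, a binding protein of insulin-like growth factors (-0.80, SE 0.04), and the chemokine CCL2 (-0.74, SE 0.08). That list had adjusted p = 0.0251, but adjusted p = 0.236 with an estimated correlation, and lost its call without KO replicate 2 of day 0 (0.0725). Targets of p53 were lower in 6 of 28 with 1 higher, and 7 and 1 adjusted over the list alone, with CDKN1A, the inhibitor p21, among them (-0.53, SE 0.07, adjusted p = 1.02e-04). That list had adjusted p = 0.0271, but adjusted p = 0.117 with an estimated correlation, and lost its call without NT replicate 2 (0.0628) or KO replicate 2 (0.0558) of day 0. Cholesterol synthesis genes were lower on day 0 in 5 of 24 with 0 higher, also adjusted over the list alone (adjusted p = 0.0196, but adjusted p = 0.34 with an estimated correlation, 0.0656 without NT replicate 1 and 0.065 without KO replicate 3 of day 0). Splicing regulators were higher on day 0 in 5 of 32 with 1 lower, also adjusted over the list alone (adjusted p = 0.0275, but adjusted p = 0.236 with an estimated correlation, 0.0656 without NT replicate 1 and 0.0503 without KO replicate 2 of day 0). Ribosomal protein genes had adjusted p = 0.0464 on day 0 toward higher, with 1 of 28 higher and 2 lower, also adjusted over the list alone, but adjusted p = 0.761 with an estimated correlation. The call ended without NT replicate 1 (0.342) or 3 (0.25) or KO replicate 1 (0.205) or 2 (0.192) of day 0.

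Homologous recombination genes were higher on day 0 in 5 of 19 cases with 1 lower, and 6 and 1 adjusted over the list alone, with adjusted p = 0.0414, but adjusted p = 0.117 with an estimated correlation. The call ended after quantile normalisation (0.104) and without NT replicate 1 (0.122) or 3 (0.0739) or KO replicate 1 (0.0713) of day 0, with a range over the camera alternatives of 0.0242 to 0.122. On day 6 they were higher in 7 of 19 with 0 lower, also adjusted over the list alone (adjusted p = 0.027, but adjusted p = 0.0957 with an estimated correlation and 0.0513 without KO replicate 1 of day 6). Glycolysis genes were higher on day 6 in 10 of 23 with 4 lower, also adjusted over the list alone (adjusted p = 0.0416, but adjusted p = 0.351 with an estimated correlation). The call ended without NT replicate 1 (0.0574) or 3 (0.0727) or KO replicate 2 (0.0874) of day 6. For the other called lists in this part the estimated correlation gave the highest adjusted p over their alternatives.

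The lists of trophoblast (adjusted p = 0.435 on day 0 and 0.367 on day 6), mesoderm and endoderm (0.887 and 0.85) and endothelium and blood markers (0.346 and 0.355) were not called between KO and NT cells, though some of their members were. On day 0, 1 of 6 trophoblast markers was higher (0 adjusted over the list alone), 1 of 4 mesoderm and endoderm markers higher and 1 lower, and 2 of 8 endothelial and blood markers higher. On day 6 the first had 3 higher and 1 lower, TFAP2A (-0.73, SE 0.12), and the second 1 higher and 1 lower, GATA6 (-0.91, SE 0.14). The third had 3 higher, ESAM among them (1.39, SE 0.12), and 0 lower, or 1 lower adjusted over the list alone. In mesoderm and endoderm markers on day 6 the median was 0.015 and the mean -0.121, and the test direction was lower. The TIP60 complex, in which MRG15 also takes part, was not called either, with 2 of 17 genes higher and 1 lower on day 0 (adjusted p = 0.584) and 2 and 3 on day 6 (adjusted p = 0.604), also adjusted over the list alone.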
